A study of Harpegnathos saltator with 22 samples.

How the data were processed

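Ovaries were dissected from single Harpegnathos saltator ants 24 h after injection of siRNA into the head, per the labels' protocols, and polyadenylated RNA was made into strand-specific libraries by the dUTP method, per the same protocols. Each of the 22 samples is 1 ant, and the labels' caste and knockdown fields place them in 4 groups: control gamergates (6), Kr-h1 gamergates (7), control workers (5) and Kr-h1 workers (4). The control siRNA is named GFP in the sample labels. The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2, without versions or settings. The genome build, annotation, strand setting and model formula are not given in the sources used here.

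The values are those of the authors' deposited table, with 13693 genes and 3 comparisons: Kr-h1 against GFP siRNA in gamergates, the same in workers, and workers against gamergates with GFP siRNA. For each, the authors gave a mean normalized count over the libraries compared (averaged over ants), a log2 fold change, a p-value and an adjusted p-value. The mean count was first recorded here as a signal and later under no fixed unit, because it belongs to a comparison of the authors and to no sample. The deposited table has 0 further value columns, so depth per library is unknown and no test from counts could be run. The planned count model was therefore replaced, as laid down before the data were examined, by the authors' own fold changes and adjusted p at 0.05, taken from the deposited table and not retested. Leave-one-out fits, splits of the samples and a replicate SD need values per ant and were not made.

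The deposited table was checked in 4 ways. The adjusted p equals a Benjamini-Hochberg adjustment of the deposited p-values over the genes that have one, to within 0.0018. It is missing for genes under a mean count of about 2.49 in gamergates, 5.12 in workers and 0.29 between castes, and these genes count as not tested. A p-value is also missing for 28, 88 and 109 expressed genes in the gamergate, worker and caste comparisons, among them yellow-g in gamergates and Tsf1 in workers. The fold change signs and group sizes were checked by predicting each knockdown comparison's mean count from the caste comparison: with the signs and sizes of the labels, the residual SD was 0.0020 (gamergates) and 0.0072 (workers) on the log2 scale. With the knockdown sign reversed it was 0.44 and 0.53, and the best other group sizes gave 0.0088 and 0.0098. Positive values therefore mean higher with Kr-h1 siRNA, or higher in workers, and the fold changes are ratios of group means without shrinkage.

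Gene symbols came from the RefSeq table of assembly Hsal_v8.6 through the number in each gene ID. There, 13681 of 13693 IDs matched and 4117 genes (30.1%) have a descriptive symbol; the others are uncharacterized by name and are never named. The symbols are those of presumed fly or bee counterparts. No coordinates are given because the authors' build is not stated. The themes of 20 gene lists were fixed before the data were examined, as patterns for product names. The reference holds no product names, and the patterns reached 51 genes, so the lists were restated as symbols after the table had been opened, when the values of 17 genes had been seen (Kr-h1, br, ftz-f1, usp, Ecr, jhamt, Nos, vas, foxo, Eip93F, Hr3, Hr38, vg, Eip74EF, E75, Hr4 and yl). The lists hold 533 genes. A further 18 families were written later, after the lists' results had been seen. For each list the called members were counted, over all genes and adjusted over the list alone, and the median log2 fold change was ranked among 10000 random lists of the same size, drawn within 20 strata of mean count. A list was not ranked with under 3 tested members. The random lists were drawn gene by gene, so a percentile treats genes as independent and does not measure the spread between ants. Genes of a list that vary together between ants can reach an extreme percentile without a response. The ovary has muscle, nerve and tracheal cells of its own, so the lists for other tissues do not separate these from attached tissue.

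Named genes followed a rule fixed before the data were examined: Kr-h1, then up to 8 genes higher and 8 lower with the largest fold change among those called, with a mean of at least 50 and a descriptive symbol, then up to 2 called members per list with the smallest adjusted p. Genes named outside that rule, such as tsl, yellow-g2 and br in other comparisons than the one that named them and the genes of the later families, were chosen after their values were seen. The result of 1 gene that the rule names is not reported here.

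The SE of each fold change was recovered as the fold change divided by the normal quantile of its p-value, which assumes a Wald test, as the DESeq2 named by the submitters runs by default. The authors' test is not named in the sources used here. The difference of the 2 knockdown responses was tested per gene with a z test on the recovered SEs over 10453 genes, with Benjamini-Hochberg adjustment. That test was added after the table had been opened, since the plan foresaw it only for deposited standard errors. On simulated data with 200 genes changed in 1 caste, it called 53% of differences of 1 on the log2 scale and 79% of differences of 2, and 4.35% of its calls were unchanged genes. Of 200 random lists, 4.5% lay outside the central 95%. Both checks drew genes independently, the first with normal errors of the recovered SEs. They therefore check the calculation alone. The Wald assumption, the error of an SE from few ants and correlation between genes were not checked by them. Alternatives were thresholds of 0.10 and 0.01 and a log2 change of at least 1, other filters on the mean count (none, 1 and 50), median centring, and removal of a lowess trend (fraction 0.2) of fold change on mean count. Chance covariance from shared control libraries was simulated 100 times from the recovered SEs. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.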

Results

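The series measured polyadenylated RNA by strand-specific sequencing in the ovaries of the ant Harpegnathos saltator, a species in which workers can leave the worker caste and become gamergates, workers that mate and lay eggs. Each ant had received siRNA against Kr-h1, a zinc-finger transcription factor of the juvenile hormone and ecdysone pathways, or against GFP as control, injected into the head, and its ovaries were taken 24 h later. There were 22 libraries, 1 per ant, in 4 groups. They came from 6 control and 7 Kr-h1 gamergates and from 5 control and 4 Kr-h1 workers. The files used here hold no values per ant: the authors' deposited table gives, for 13693 genes and 3 comparisons, a mean normalized count, a log2 fold change, a p-value and an adjusted p. The depth of each library is therefore unknown. The summed mean normalized counts were 11949157 in the gamergate knockdown comparison, 10042271 in the worker one and 11307846 between castes. Errors given below as SE were recovered from the deposited fold changes and p-values. They were smaller in gamergates (median 0.13 on the log2 scale) than in workers (median 0.21), where fewer ants were compared.

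Kr-h1 itself (LOC112589664) was the targeted gene, and because the siRNA went into the head, its ovary level asks whether the knockdown also reached the ovary. Kr-h1 had a mean of 42.3 normalized counts in gamergate ovaries and 38.7 in worker ovaries in the authors' deposited table. Its log2 fold change in that table was 0.26 in gamergates (recovered SE 0.47, adjusted p = 0.734, DESeq2) and -0.48 in workers (recovered SE 0.70, adjusted p = 0.706, DESeq2). The 2 fold changes differed by 0.74 with an SE of 0.85, and neither passed the threshold, so no change of Kr-h1 in the ovary was detectable with this spread and a change of moderate size is not excluded. Kr-h1 also did not pass between castes (log2 0.36 in the authors' deposited table, adjusted p = 0.625, DESeq2).

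In gamergate ovaries, the named genes with a mean of at least 50 and the largest decreases after Kr-h1 siRNA were ndl, Cad74A, Cad88C and br, and those with the largest increases were bnb, Miox, Tpx-4 and Tret1. The serine protease gene ndl (nudel, LOC105181294), which follicle cells need for the eggshell, fell most among the named genes, by 3.87 on the log2 scale in the authors' deposited table, 14.6-fold (recovered SE 0.51, adjusted p = 8.74e-11, DESeq2). The ecdysone-pathway transcription factor gene br (broad) had a log2 fold change of -2.07 in the deposited table (recovered SE 0.62, adjusted p = 0.0128, DESeq2), and the nuclear receptor genes Hr3 and Hr4 stood at -1.83 (adjusted p = 8.71e-08) and -0.86 (adjusted p = 6.01e-04). The cadherin genes Cad74A and Cad88C fell by 3.06 and 2.48 in the authors' deposited table. The remaining genes among the 8 with the largest decreases there were Chsy, a chondroitin synthase (-1.95), the potassium channel Elk (-1.87) and the endocytic protein Past1 (-1.71). Among called genes with a symbol and a mean of at least 50, bnb rose most in the authors' deposited table, by 2.92 (recovered SE 0.77, adjusted p = 0.0052, DESeq2). Among genes with a mean of at least 50, it was followed there by Miox, an inositol oxygenase (1.54, adjusted p = 2.06e-08), the peroxiredoxin-like Tpx-4 (1.43), the trehalose transporter Tret1 (1.40), the lipid carrier apolpp (1.38), the T-box factor bi (1.33), and the cell-surface or junction genes pot (1.21) and hoka (1.18). In all, 997 genes were higher and 657 lower of 11145 tested in the authors' deposited table, and 129 and 74 of them by at least 2-fold. The median size of a called change was 0.37 on the log2 scale.

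By gene list in gamergates, the medians of the insulin and TOR list and of the ERK and EGFR list lay high. Both lists hold activators and inhibitors of their pathways, so their medians give no direction of signalling. The random lists were not matched on transcript length, so a bias by length between the groups was not tested. Of 25 insulin and TOR genes, 10 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.20 at the 99.9th percentile of 10000 random lists matched on mean count. Those with the smallest adjusted p in the authors' deposited table were the PI3-kinase adaptor Pi3K21B (0.51, adjusted p = 3.49e-05, DESeq2) and Lnk (0.34). Other members that rose there included Sesn (0.72), REPTOR (0.44), foxo (0.29) and PRAS40 (0.27), and the 2 that fell were Rheb (-0.24) and Lst8 (-0.21). Of 17 ERK and EGFR genes, 7 rose and none fell (9 and 0 adjusted over the list alone; percentile 99.9). The EGF receptor gene Egfr stood at 0.57 in the deposited table (recovered SE 0.06, adjusted p = 2.20e-14, DESeq2) and the pathway's feedback inhibitor sty (sprouty) at 0.81 (adjusted p = 2.58e-04). Germline and oogenesis genes had 7 members higher and 1 lower of 35 (7 and 1 adjusted over the list alone; percentile 99.2), among them hts (0.32) and BicD (0.46) in the authors' deposited table. That list's percentile became 97.47 against genes with a symbol only, just inside the central 95%. The yolk and lipid list had 1 call of 6, apolpp (percentile 96.6). Of 8 RNA interference genes, 2 rose, gw (0.43) and drosha (0.30) in the deposited table. The other 6 were not called, among them AGO2 (-0.06) and Dcr-2 (0.15). Of the 8, 7 were positive and 1 negative, and the median of 0.14 lay at percentile 93.3, inside the central 95%. A small joint rise of the list is therefore neither shown nor excluded. Cell cycle genes had 6 higher and 4 lower of 72, with Orc1 at 0.26 and Psf3 at -0.40 in the authors' deposited table. In the juvenile hormone and ecdysone list, 3 of 24 tested members rose and 3 fell (5 and 3 adjusted over the list alone), so its median of 0.02 lay at percentile 56.3. Of 4 eggshell genes with an adjusted p (median -0.53, percentile 0.06), ndl fell and fs(1)N rose (0.37, adjusted p = 0.0495 in the authors' deposited table), and fs(1)N lost its call when genes of low mean were kept in the adjustment (adjusted p = 0.0563). The eggshell genes yellow-g and yellow-g2 had log2 fold changes of -7.54 and -3.59 in the deposited table. Neither has a p-value or an adjusted p there, for a reason not stated, so they are not counted.

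The medians of the lists of protein synthesis, turnover and respiration lay lower in gamergates, by small amounts. Their ranks treat genes as independent and are not tests across ants, and a bias by transcript length was not tested here either. Of 56 respiratory chain genes, 7 fell and none rose (7 and 0 adjusted over the list alone), with a median of -0.21, lower than in all 10000 random lists. Examples in the authors' deposited table were ND-B12 (-0.33) and NdufV3 (-0.35). Of 30 proteasome genes, 6 fell (16 adjusted over the list alone; median -0.17, percentile 0.07), including Prosalpha5 (-0.34) and Rpn11 (-0.23) in that table. Of 57 cytosolic ribosomal protein genes, 2 fell (2 adjusted over the list alone), for example RpLP1 (-0.45) in the deposited table, with a list median of -0.20, also lower than in all random lists. That count is no larger a share than the 657 lower of all 11145 genes tested. Among 26 chaperone genes, 2 rose and 3 fell (3 and 5 adjusted over the list alone), and the risers in the authors' deposited table were Hsp90 (0.55, adjusted p = 6.39e-05, DESeq2) and Hsc70Cb (0.25). Immune genes had 1 higher, Toll-7 (0.60), and 1 lower, Fadd (-0.26), of 27 in the deposited table. Ir25a rose (0.54 in the authors' deposited table), as the 1 called gene of 15 tested in the chemosensory and detoxification list, whose median lay at percentile 10.1, but 0.48 against genes with a symbol only.

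Markers of tissues other than ovary were among the genes that rose in gamergates. Of 13 fat body genes, 5 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.74, higher than in all random lists. Apart from apolpp, Vhdl stood at 0.92 in the authors' deposited table. Of 25 muscle genes, 4 rose (median 0.43, higher than in all random lists), with Lmpt at 0.81, Mef2 at 0.44, Msp300 at 0.34 and tmod at 0.30 in the deposited table. The list had 18 positive and 7 negative members, and its myosin and troponin genes were not called. Among the negative were TpnT (-0.35) and TpnCI (-0.18). Of 40 nerve genes tested, 10 rose (13 higher and 1 lower adjusted over the list alone; percentile 98.9, but 81.2 against genes with a symbol only), with para at 0.56 and nAChRalpha1 at 0.96 in the authors' deposited table. None of the 5 haemocyte genes was called (median -0.24, percentile 6.61, but 2.34 against genes with a symbol only), and 1 was higher at an unadjusted p under 0.05. In the deposited table, 2 of 19 cuticle and trachea genes fell, Cpap3-d (-2.16) and Gasp (-2.42), 1 adjusted over the list alone. Their mean counts were low, 8.7 and 3.6. AQP fell (-0.71) as 1 of 2 gut genes tested, a call lost when genes of low mean were kept in the adjustment (adjusted p = 0.0554).

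**Figure D1:**
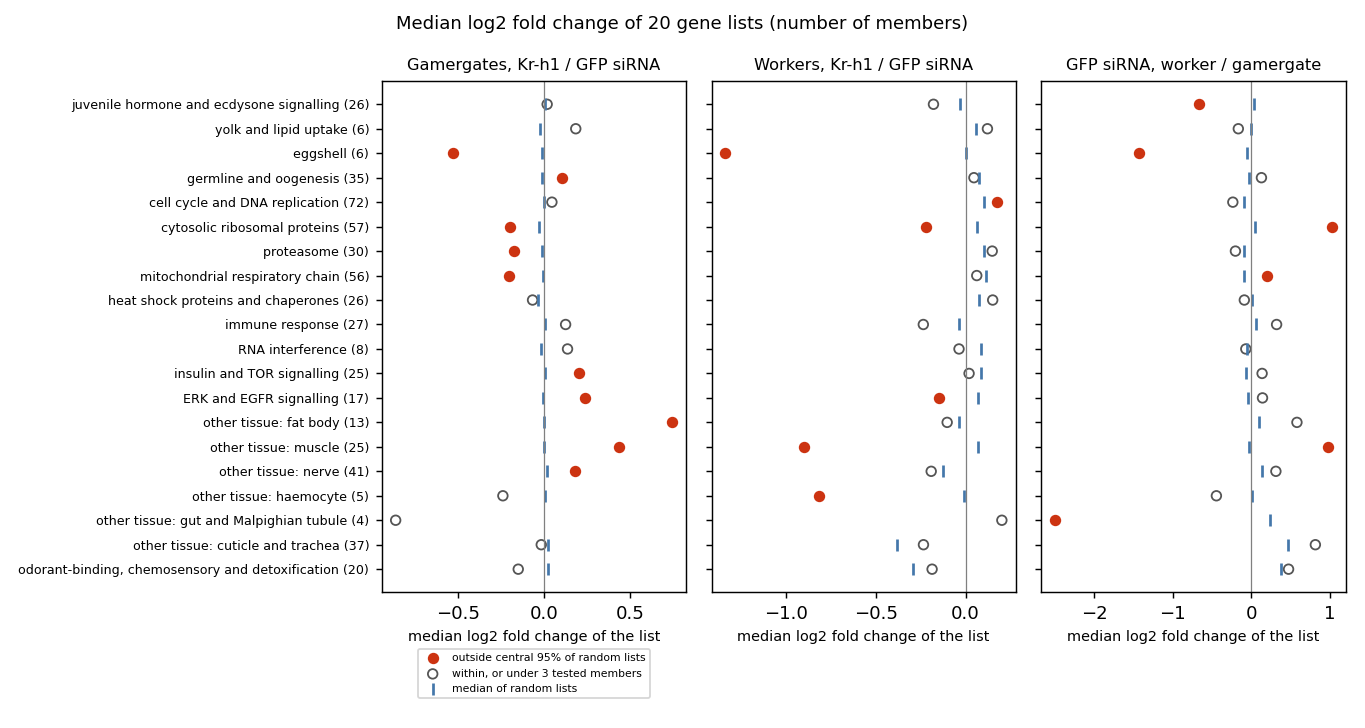
Median log2 fold change of each of the 20 gene lists (vertical order, number of members in brackets) in the 3 deposited comparisons (panels, log2 scale). Filled points lie outside the central 95% of 10000 random lists matched on mean count, open points do not or have under 3 tested members, and the tick is the median of the random lists; the muscle list stands at 0.43 in gamergates, -0.90 in workers and 0.98 between castes.

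In worker ovaries, dib and sro rose after Kr-h1 siRNA and eggshell genes fell. The cytochrome P450 gene dib (disembodied) and the dehydrogenase gene sro (shroud), which both act in ecdysteroid synthesis, stood at 1.43 (recovered SE 0.28, adjusted p = 2.73e-04, DESeq2) and 1.20 (recovered SE 0.27, adjusted p = 0.0025, DESeq2) in the authors' deposited table. The sulfakinin neuropeptide gene Dsk rose most among the named genes, by 2.93 in that table (recovered SE 0.77, adjusted p = 0.0119, DESeq2). After dib, it was followed in the deposited table, among genes with a mean of at least 50, by the GABA receptor subunit Lcch3 (1.33), Tre1, a receptor known from germ cell migration (1.28, adjusted p = 9.65e-05), tan (1.23), Prdm13 (1.11) and sel (1.08, adjusted p = 8.72e-04). The eggshell genes yellow-g2 and yellow-g had the lowest values among the named genes, -6.38 (recovered SE 1.65, adjusted p = 0.0101, DESeq2) and -5.01 (recovered SE 1.18, adjusted p = 0.00358, DESeq2) in the authors' deposited table. Both belong to a multigene family, so their counts are uncertain if reads were split between copies. Their means in workers were 56.5 and 178.5, over 5 control and 4 Kr-h1 ants. No follicle stage is recorded, so different numbers of late follicles between these ants are not excluded. With ndl (-1.53, adjusted p = 3.17e-04) and tsl (-1.14) in the deposited table, 4 of 6 eggshell genes fell (5 adjusted over the list alone), and the list median of -1.34 was lower than in all 10000 random lists. The other genes with a mean of at least 50 among the largest decreases in the authors' deposited table were the bestrophin Best2 (-2.35, adjusted p = 2.97e-05), pio (-1.73), the channel trp (-1.68), the BMP ligand gbb (-1.63) and the yellow-family gene Y-e3 (-1.54). In all, 236 genes were higher and 284 lower of 10577 tested in the authors' deposited table, and 90 and 190 of them by at least 2-fold.

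Outside the eggshell list, few members of any list were called in workers. In the juvenile hormone and ecdysone list dib and sro were the 2 called members of 24 (median -0.18, percentile 10.1). Of 6 yolk and lipid genes 1 was called, mgl (megalin), at -1.19 in the authors' deposited table (adjusted p = 0.0177, DESeq2). Cell cycle genes had 2 higher of 72, Orc4 (0.74) and polo (0.63) in the deposited table, with a median of 0.18 at percentile 98.9. Single calls in the authors' deposited table were pch2 in the germline list (0.63), the ER chaperone Gp93 (0.88), the translation repressor Thor (0.48), Tollo in the immune list (-1.65), Hex70c in the fat body list (-2.70), nAChRalpha2 in the nerve list (-0.67) and Pvr in the haemocyte list (-0.94). Of these genes, trp, polo, pch2, Thor, Tollo, Hex70c and nAChRalpha2 were no longer called once the trend of fold change on mean count was removed. Hex70c and Tollo had low mean counts in workers, 13.6 and 23.8. No muscle gene of 25 was called, 8 were lower and 0 higher at an unadjusted p under 0.05, and the list median of -0.90 was lower than in all random lists. The 5 haemocyte genes had a median of -0.82 (percentile 0.77) and the 17 ERK and EGFR genes, none called, a median of -0.15 (percentile 1.21). The ribosomal list had no call of 57 and a median of -0.22, again lower than in all random lists. That rank treats its genes as independent and is not a test across ants. No member was called by the adjusted p of DESeq2 in the proteasome, respiratory chain, RNA interference, cuticle and trachea, chemosensory, or gut lists of the authors' deposited table. At an unadjusted p under 0.05, 2 proteasome and 2 respiratory chain genes were higher, 3 cuticle and trachea genes lower, 1 chemosensory gene higher and 3 lower, 1 ERK and EGFR gene lower, and 0 ribosomal, RNA interference or gut genes in either direction. Adjusted over the list alone, 2 members were called higher in each of the germline, chaperone and insulin lists, 3 lower in each of the immune and haemocyte lists, 1 in each direction in the fat body list and 0 in the nerve list.

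The worker fold changes also depended on abundance. The 2683 tested genes with a mean under 100 had a median of -0.46, and the 2849 with a mean of at least 1000 had a median of 0.11. In gamergates the corresponding medians were 0.03 and -0.01. Between castes, workers over gamergates, they were 0.53 and -0.08, a trend in the other direction in a comparison that shares the control workers.

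Over all genes, the responses of the 2 castes were not alike, although some of the largest decreases were shared. Over the 10453 genes tested in both, the log2 fold changes had a Spearman correlation of -0.15 across genes, which are not independent replicates, and the 2 comparisons share no library. Of genes called in both castes, 53 had opposite signs and 9 the same sign, against 39.3 and 38.2 expected for independent lists. Of the 53, 38 were higher in gamergates and lower in workers (25.2 expected) and 15 the reverse (14.1 expected). The 9 with the same sign included ndl, Elk, Chsy and Past1, all lower in both castes in the authors' deposited table. The eggshell genes yellow-g and yellow-g2 were negative in both as well (-7.54 and -3.59 in gamergates, -5.01 and -6.38 in workers). Without a p-value in gamergates, they are left out of these counts. The expected numbers treat genes as independent and do not cover variation that many genes share between ants. A z test of the difference of the 2 responses, with the recovered SEs, called 1093 genes. Signs were opposite for 59.5% of genes called in either caste and for 55.4% of all genes tested in both. The response was more positive in gamergates for 542 and in workers for 551. Under this test, the response of dib was lower in gamergates than in workers by 1.43 (SE 0.31, adjusted p = 5.78e-04, z test), and that of sro by 1.31 (SE 0.29, adjusted p = 9.47e-04, z test). Hr3 differed by -1.67 (SE 0.42, adjusted p = 0.00393, z test) and Hr4 by -1.12 (adjusted p = 0.00361), but br did not pass (-1.09, adjusted p = 0.42), nor did Egfr (0.76, adjusted p = 0.0638). Although ndl fell in both, its decrease was larger in gamergates, by -2.34 (SE 0.60, adjusted p = 0.00393, z test).

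**Figure D2:**
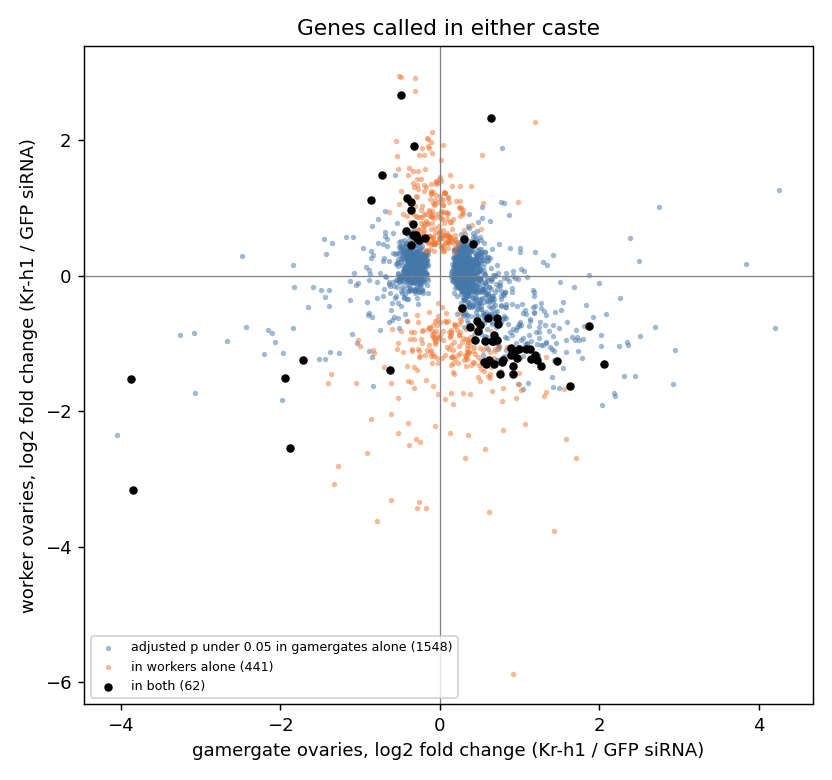
Log2 fold change after Kr-h1 siRNA in gamergate ovaries (horizontal) and worker ovaries (vertical) for each gene called in either caste in the authors' deposited table. Black points are the 62 genes called in both, of which 53 lie in the quadrants of opposite sign.

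**Figure D3:**
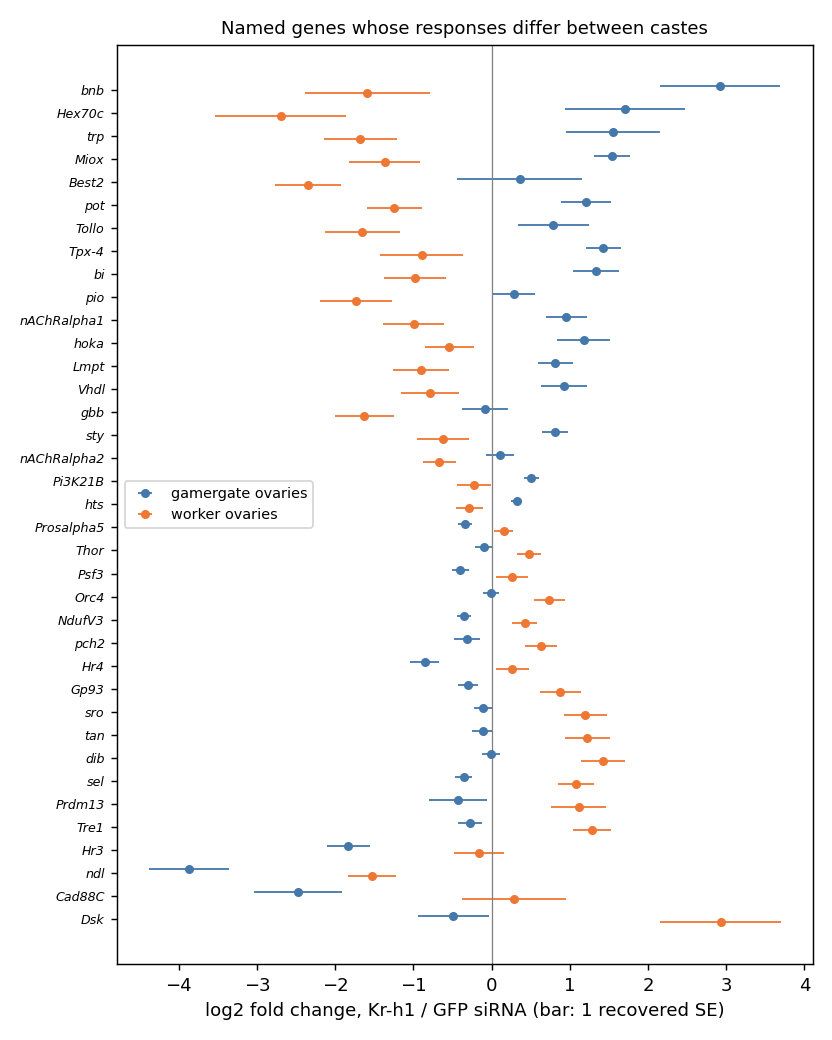
Log2 fold change after Kr-h1 siRNA (horizontal, log2 scale) in gamergate and worker ovaries for the named genes whose responses differed between castes by the z test, ordered by the difference. Points are the authors' deposited values, bars 1 recovered SE; ndl lies below 0 in both castes.

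With the control siRNA, worker and gamergate ovaries differed in 53.2% of the genes tested: 3355 were higher in workers and 3204 higher in gamergates of 12338 in the authors' deposited table, 1765 and 1452 of them by at least 2-fold. Higher in workers in that table were bnb (5.93, worker over gamergate), B-gluc1 (5.09), the giant muscle protein gene sls (4.71), trp (4.26), jv (3.88), bi (3.88), the Hox gene Ubx (3.72) and the transglutaminase Tg (3.72). Higher in gamergates in the authors' deposited table were flz (-5.56), dsb (-5.50), the cathepsin CtsL4 (-5.35), the fatty acid elongases bond (-5.32) and sit (-4.63), Hbg3 (-4.78), St2 (-4.70) and the histidine decarboxylase Hdc (-4.52). Genes for ecdysteroid synthesis were among those higher in gamergates: sad stood at -3.99 (recovered SE 0.44, adjusted p = 3.92e-18, DESeq2) and shd at -2.53 (recovered SE 0.19, adjusted p = 4.40e-38, DESeq2) in the deposited table. The juvenile hormone and ecdysone list had 13 members higher in gamergates and 4 higher in workers of 26 (median -0.67, percentile 0.04). Of 57 cytosolic ribosomal protein genes, 53 were higher in workers (median 1.03), for example RpS3 at 1.71 and RpL15 at 1.49 in the authors' deposited table. Respiratory chain genes had 23 higher in workers and 3 higher in gamergates of 56 (percentile 99.99), although CytC was higher in gamergates (-1.39 in the deposited table).

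Cell cycle genes had 32 members higher in gamergates and 10 higher in workers of 72 (median -0.23, percentile 2.71, but 0.27 against genes with a symbol only), with Cdk1 at -1.10 and borr at -1.03 in the authors' deposited table. Of 5 eggshell genes tested, 3 were higher in gamergates, ndl (-3.96), tsl (-1.43) and Cad99C (-1.06) in that table. The yolk receptor gene yl was higher in gamergates (-1.07) and apolpp in workers (3.03) in the authors' deposited table, in a list with 1 of 6 higher in workers and 2 higher in gamergates. The germline list was split, 13 higher in workers and 11 higher in gamergates of 35, with pch2 (-1.56) and papi (-1.60) on the gamergate side in the deposited table. Proteasome genes had 2 and 9 of 30, chaperones 6 and 9 of 26, immune genes 11 and 3 of 26, RNA interference genes 1 and 2 of 8, insulin and TOR genes 8 and 3 of 25, and ERK and EGFR genes 6 and 2 of 17, in each case workers first. Examples in the authors' deposited table were Rpt4 (-0.69), the ER chaperone Hsc70-3 (-1.56), the immune gene cGlr1 (-3.59), gw (1.45), the insulin-binding ImpL2 (-2.79) and the EGFR-pathway factor pnt (1.50). Of these, cGlr1, gw and ImpL2 went against the larger count of their lists. Markers of other tissues differed as well: 18 of 25 muscle genes were higher in workers and 1 in gamergates (median 0.98, higher than in all random lists), 7 and 3 of 12 fat body genes, 16 and 10 of 40 nerve genes, 2 and 3 of 5 haemocyte genes, 0 and 2 of 3 gut genes, 8 and 4 of 29 cuticle and trachea genes, and 6 and 5 of 19 chemosensory and detoxification genes. Adjusted over the list alone, the counts were the same except for 4 eggshell and 8 proteasome genes and 11 nerve genes higher in gamergates and 6 cuticle and trachea genes higher in workers. The 2 castes with the Kr-h1 siRNA were not compared here, since the authors' deposited table as used here holds no such comparison.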

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

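Apart from the test of calls kept without the abundance trend, which was chosen after the trend had been seen but before its own result was, the tests in this part were chosen after the results had been seen, and the z test of the difference of responses was added after the table had been opened. No test for outlying ants could be run here without values per ant. Why 28, 88 and 109 expressed genes in the gamergate, worker and caste comparisons have no p-value is not stated in the sources used here. Outlying ants stay possible for those genes. The z test called 1093 genes whose response to Kr-h1 siRNA differed between gamergate and worker ovaries at an adjusted p under 0.05.

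Among the named genes of the knockdown comparisons, the following differences, gamergate minus worker on the log2 scale, passed that test. The response was more positive in gamergates for bnb (4.51), Hex70c (4.40), trp (3.23), Miox (2.91), Best2 (2.70), pot (2.45), Tollo (2.44), Tpx-4 (2.32), bi (2.31), pio (2.02), nAChRalpha1 (1.96), hoka (1.72), Lmpt (1.71), Vhdl (1.71), gbb (1.54), sty (1.42), nAChRalpha2 (0.78), Pi3K21B (0.73) and hts (0.60). It was more positive in workers for Dsk (-3.42), Cad88C (-2.76), ndl (-2.34), Hr3 (-1.67), Tre1 (-1.56), Prdm13 (-1.54), sel (-1.44), dib (-1.43), tan (-1.34), sro (-1.31), Gp93 (-1.18), Hr4 (-1.12), pch2 (-0.95), NdufV3 (-0.78), Orc4 (-0.75), Psf3 (-0.66), Thor (-0.58) and Prosalpha5 (-0.49).

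The gamergate response followed the difference between castes: of 991 genes higher after knockdown, 573 were higher in workers and 26 higher in gamergates, against 275.3 and 284.1 for independent lists, and of 656 lower, 386 were higher in gamergates and 18 in workers (188.1 and 182.2). Both comparisons use the control gamergates, which alone add covariance. Over 8243 genes with a mean of at least 50, the covariance was 0.192 against a simulated 0.0222 (correlation 0.57 against 0.45). The ratio to the highest of 100 simulations was 6.07, so noise of single genes in the shared libraries did not account for the whole covariance. The recovered SEs hold no correlation between genes. Variation of the control ants that many genes share was therefore not covered, and the shared libraries are not excluded as the cause. The medians of the muscle and fat body lists lay at percentile 100, so more of such tissue in the Kr-h1 gamergate samples may contribute. In the authors' deposited table the sarcomere genes Mhc and sls had 0.78 and 0.97 and did not pass. The haemocyte list had a median of -0.24 but was split, with 2 members positive and 3 negative. The 2 positive, PPO (0.84) and Pxn (0.59), were higher in control workers (2.18 and 1.31), and the 3 negative were higher in control gamergates. That median therefore does not argue against more tissue of other kinds. The abundant Tm1 (mean 6843) had -0.03. Between castes, however, Tm1 had 0.08 where the muscle list had a median of 0.98, so a flat Tm1 does not argue against more muscle. A change of state of the ovary itself stays open, untested.

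Worker responses ran the other way. Of 236 genes higher after knockdown, 212 were higher in gamergates and 2 in workers (64.7 and 70.4 for independent lists). The covariance with the caste difference was -0.207, below the lowest of 100 simulations of the shared worker controls (-0.0409). The correlation of -0.44 was no stronger than the simulated -0.52, and these simulations also leave out variation that many genes share. The shared worker controls are therefore not excluded as the cause. Genes with a mean under 100 fell in the median by 0.46, and without the abundance trend 51.8% of the lower calls were kept, too few to exclude a trend of normalization and too many to account for the calls by it. The median of the muscle list lay at percentile 0, with 22 members negative and 3 positive, but those of the fat body and nerve lists lay at 32.6 and 26.6. The fat body rank leaves out Tsf1 (-1.04), which has no p-value in workers. Less tissue of other kinds in the Kr-h1 worker samples therefore stays open. The abundant Tm1 had 0.00 in the authors' deposited table, but it did not follow the muscle list between castes and so does not argue against less muscle. Low-mean genes with a positive gamergate response had a median lower by 0.118 than the others (difference -0.118), which does not settle whether a loss of low counts alone is involved.

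The decrease of ndl, br, Hr3 and Hr4 in gamergates could come from ovaries holding different numbers of late follicles. The median recovered SE of these genes, 0.39, lay at percentile 98.2 of lists matched on mean count (median 0.15), but at percentile 3.25 of lists of called genes with a like size of fold change (median 0.58). The high spread goes with the large fold changes for which these genes were chosen, so it decides nothing on follicle stages. No stage is recorded in the labels used here, and a response to the siRNA stays open. The decrease of eggshell genes in workers has the same limit and was not tested for it.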

How the results depend on the processing

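Removing the abundance trend, centring, the mean filter of 50 and the symbol-only background were chosen after the data had been seen, removal of the trend before its own results were. No paired analysis was possible because the deposited table holds no values per ant, so replicate numbers cannot be used. For the same reason other normalizations and count tests, the per-library filter, leave-one-out, the fit of all 4 groups, surrogate variables, other pseudocounts, fry, camera and library-size scaling of Kr-h1 were not run, nor were other splits of the samples, so whether chance can be excluded by regrouping is not known. The counts of called genes kept within 1.5 times under the mean filters, centring and trend removal, in all 3 deposited comparisons, and under those of them that were run (a mean of 50, centring and trend removal) for the difference of responses. With the threshold they moved by construction: at 0.10, 2736 genes in gamergates, 1019 in workers and 1915 differing between castes in response; at 0.01, 580, 119 and 359; at a log2 change of at least 1, 203, 280 and 589, and 3217 between castes. Without the trend, the z test called 892 genes, 686 of them among the 1093, and the worker split was 227 higher and 215 lower. The correlation of the responses was -0.18 over genes with a mean of at least 50 and -0.17 without the trend; the cause was not tested. At an adjusted p under 0.10 in both, 55 genes had the same and 161 opposite signs. List members called were 155 in gamergates and 34 in workers at 0.10, and 192 and 88 at an unadjusted p under 0.05. Of 128 named gene results, 121 kept their call without the trend, 127 with centring and 125 without a filter, and none changed sign. The number of lists outside the central 95% was 10, 6 and 7 against genes with a symbol, where it had been 10, 6 and 6. Kr-h1 had an adjusted p of 0.703 to 0.985 over its alternatives in workers and 0.734 to 0.774 in gamergates. Precision was limited by the worker comparison, with a median recovered SE of 0.21.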

Other observations

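The families in this part were written after the lists' results had been seen, and their tests with them. As for the lists, their ranks treat genes as independent and were not matched on transcript length. In gamergate ovaries, the families of ER translocation and of mitochondrial ribosomal proteins had low medians. Of 53 genes of ER translocation and protein folding, 27 fell and none rose, with a median of -0.25, lower than in all 10000 random lists. Sec61alpha, the pore of the ER translocon, stood at -0.70 (adjusted p = 0.00157) and Ostgamma at -0.46 in the authors' deposited table. Of 23 COPI, COPII and Golgi traffic genes, 6 fell, including KdelR (-0.51 in the deposited table), but the family median of -0.10 lay at percentile 7.26. A prediction of a joint decrease of the ER and Golgi families was written and then left out, since 3 patterns are weighed here, and by its own bound it would not have been met. Of 70 mitochondrial ribosomal protein genes, 22 fell (median -0.25, lower than in all random lists), for example mRpS34 at -0.57 in the authors' deposited table. In workers that family had no call by the adjusted p of DESeq2 and 5 members higher at an unadjusted p under 0.05, with a median of 0.20 (percentile 99.6), and the z test called 10 members, all more positive in workers. Of 11 steroid hormone synthesis genes, 2 rose in workers, dib and sro, and the family median of 0.08 lay at percentile 59.9. The same ER family was lower in control workers than in control gamergates, with 30 of 53 lower and 1 higher (percentile 0.12), and the gamergate comparison shares those control gamergates. In worker ovaries 1 of the 53 rose and 1 fell, and the z test called 10 of them, all more positive in workers.

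Families of cell contacts and of local signals moved up in gamergates. Of 15 BMP and TGF-beta genes 6 rose (percentile 99.7), among them the receptor babo (0.56) and the glypican dally (0.40) in the authors' deposited table. Of 16 Notch genes 5 rose and 1 fell (percentile 99.9), with Delta at 0.65 in the deposited table, and 3 of 10 Hippo genes rose (percentile 99.5), with wts at 0.35. In workers, matrix and junction genes had low medians: -0.63 over 15 matrix genes and -0.30 over 21 junction genes, both lower than in all random lists, with 2 members of each called lower, Timp (-0.63) and if (-1.18), and pasi1 (-1.11) and Nrx-IV (-0.75), in the authors' deposited table. The z test called 6 members of each of these families, all more positive in gamergates. Muscle markers moved the same way (median -0.90 in workers, 0.43 in gamergates), while haemocyte markers had negative medians in both (-0.82 in workers, -0.24 in gamergates at percentile 6.61). The haemocyte list was split in gamergates, with 2 members positive and 3 negative. Fat body markers had 0.74 in gamergates but -0.10 in workers (percentile 32.6). Such tissues express matrix and junction genes too. In gamergates, the matrix family (percentile 99.8, 2 of 15 higher) and the junction family (percentile 98.6, but 96.5 against genes with a symbol only, 5 of 21 higher) also had medians outside the central 95%, as did RNA polymerase II and general transcription factors (percentile 1.4, 2 higher and 4 lower of 30). In workers the latter family had 0 calls by the adjusted p of DESeq2 and 7 members higher at an unadjusted p under 0.05, with a median of 0.21 (percentile 98.8), and the z test called 6 members, all more positive in workers.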
